A study of Homo sapiens with 33 samples.

How the data were processed

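Total RNA from THP-1 cells, a human monocytic leukaemia line, was measured on 33 Affymetrix HG-U133 Plus 2 arrays, each from a separate culture well. Cells had received all-trans retinoic acid (RA, 20 nM, in ethanol), tumor necrosis factor (TNF, 5 ng per ml), both, or vehicle. The 4 groups of experiment 1 were harvested at 40 h and comprised 6 vehicle, 5 RA, 5 TNF and 5 RA plus TNF wells. TNF was present for 24 h, and in the combined treatment RA was present for 40 h. Experiment 2 held 2 wells after 2 h of RA, 2 after 6 h and 3 after 16 h, with 5 vehicle wells harvested at 16 h.

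The deposited values are log2 ratios of each probe set's signal to the median signal of its own array, so that the median of each array is 0. Signals came from GCOS, the Affymetrix operating software, per the submitters' processing notes. Its version is not given in the sources used here. The settings, the scaling target and the centring step are not stated there either, and the last was read from the values. Powers of 2 of the distance from an array's lowest value were multiples of 0.1 signal units, within 0.006 units, for 100% of the signals under 8 units, which set the log base at 2 and the lowest value at 1 signal unit. GCOS signals were recovered on that basis. Their trimmed mean, with 2% removed at each end, was 150 on every array. The recovered array medians ranged from 18.9 to 45.2 units, so centring on the median applied a different factor to each array. Centring and scaling remove any change in total RNA per cell. For arrays, the number of arrays limits the precision.

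The array record numbers in the labels fall into 2 separate runs, called array set 1 (12 arrays) and array set 2 (21 arrays) here. Each group of experiment 1 has 3 arrays in set 1, with 3 vehicle arrays and 2 arrays of each treated group in set 2. All arrays of experiment 2 are in set 2. The replicate numbers were not used as pairs.

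The array holds 54675 probe sets, of which 62 AFFX controls were left out. A gene was listed for 42898 probe sets. Probe sets with a single symbol (41097) were kept, and those with several symbols (1801) or none (11777) were not used. Of the kept probe sets, 41043 matched the human reference gene table by gene number. Each of the 19775 genes was represented by its probe set of highest mean over all arrays. Probe sets whose mean linear value over the arrays of a fit lay below the median of all probe sets (0.882 of the array median in experiment 1, 0.891 in experiment 2) were removed, which left 12398 and 12507 genes. CYP26A1, CYP26B1 and RARB fell below this filter.

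Values entered limma 3.58.1 (R 4.3.3, data.table package version 1.17.8) as deposited, without further normalization. Linear models were fitted with lmFit and moderated with eBayes with an intensity trend, and a gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05. All adjusted p-values for single genes below are from these limma fits. Experiment 1 was fitted over its 21 arrays with the array set as a covariate, which left 16 residual degrees of freedom. Its contrasts were RA, TNF and RA plus TNF against vehicle, RA plus TNF against each single treatment, and the interaction, which is the RA effect under TNF minus the RA effect without TNF. Experiment 2 was fitted over 17 arrays of set 2, with 12 residual degrees of freedom. Its reference was 8 vehicle arrays, 5 harvested at 16 h and 3 at 40 h, and the 40 h time point took the 2 RA arrays of set 2. The array set 2 arrays of RA and vehicle at 40 h served in both experiments. Errors beside a log2 fold change are standard errors.

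The genes, filters, contrasts, lists and alternatives were fixed before the data were examined, apart from those named as chosen later. Named genes followed a fixed rule. In every comparison CYP26A1, CYP26B1, DHRS3, RARB, TGM2, CD38, ITGAM, CD14, NFKBIA, TNFAIP3, TNF, IL1B and CXCL8 were followed where they passed the filter. For RA, TNF and RA plus TNF against TNF, the 8 largest called rises and the 8 largest called falls with the same sign in both array sets were taken. The rule took 8 each way at 16 h, 4 each way at 2 h and 6 h, 6 each way for the interaction, and up to 4 members of each list with the smallest adjusted p.

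The 21 gene lists covered retinoid metabolism and receptors, RA response in myeloid cells, NF-kB target genes, cytokines and chemokines, interferon response, antigen presentation, monocyte and macrophage markers, immature myeloid genes, neutrophil granule genes, cell cycle, cell cycle arrest, apoptosis and TNF receptor signalling, complement, oxidative burst and microbial killing, sterol synthesis, lipid handling, matrix proteases and inhibitors, and stress response, with lymphocyte, erythroid and megakaryocyte, and epithelial and fibroblast markers for other cell types. A probe set was found for 408 of their 458 members. Lists were tested with camera (limma) at a preset correlation of 0.01, with BH adjustment over the lists of a comparison, and again with a correlation estimated from the data. In each list the calls were also counted with p-values adjusted over the list alone.

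The alternatives were other brightness filters, quantile normalization, every probe set, removal of cross-hybridising (_x_at) probe sets, eBayes without a trend, other sets of arrays and covariates, a block on the replicate number, and each array left out in turn. Alternatives added after the data were seen used recovered signals with pseudocounts of 20, 2 and 80, centring on the genes tested, and the 3 prime to 5 prime ratio of ACTB as a covariate. Array quality was compared between groups by exact permutation tests, two-sided. The models were checked on simulated data with 200 genes changed per comparison. In these simulations the RA comparison at 40 h recovered 62.7% of 2-fold and 87.9% of 4-fold changes over 12398 genes. The interaction recovered 23.9% and 72.7%, and over 12507 genes the 6 h comparison recovered 44.8% and 78.8%. Figures were drawn with matplotlib 3.10.9.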

Results

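Transcript levels were measured in THP-1 cells, a line grown from a human monocytic leukaemia, with 1 array per culture well. At 40 h there were 6 vehicle wells, 5 wells with RA, 5 with TNF for the last 24 h and 5 with both. The RA time course added 2 wells at 2 h, 2 at 6 h, 3 at 16 h and 5 vehicle wells at 16 h. The arrays had no missing probe sets and no counts, so the depth of each array was read from its signals. Between 13 and 2964 probe sets per array lay at the floor of 1 signal unit. The 75th percentile of the deposited values, relative to the array median, ran from 1.604 to 2.725. Pairs of replicate arrays within a group correlated across genes at r = 0.844 to 0.959. Transcripts of other cell types stayed low: the lymphocyte markers had a median signal of 21.2 units, the erythroid and megakaryocyte markers 20.8 and the epithelial and fibroblast markers 19.2, against array medians of 18.9 to 45.2. Their brightest members were NKG7 (237 units), EPOR (179) and COL1A1 (79.8).

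Array medians, the 3' to 5' ratios of GAPDH and ACTB and the markers of other cell types were compared between the groups of 9 comparisons in 54 exact permutation tests, and none passed BH adjustment (smallest adjusted p = 0.798). None of these permutation tests could give a p under 0.005, so no single difference could pass adjustment over 54 tests. Differences in quality between groups are therefore not excluded. The log2 ACTB ratio was 1.31 ± 0.33 in array set 1 (SD, n = 12) and 0.51 ± 0.28 in set 2 (SD, n = 21). In experiment 1 it was 0.791 ± 0.283 with RA plus TNF (SD, n = 5) and 1.08 ± 0.53 in vehicle (SD, n = 6). RA alone was at 1.07 ± 0.581 and TNF alone at 1.05 ± 0.509 (SD, n = 5 each). Whether this ratio accounts for differences between the array sets was not tested. The arrays after 2 h and 6 h of RA had recovered medians of 23.2 ± 1.63 and 22.2 ± 4.74 units (SD, n = 2 each), against 29.4 ± 3.46 (SD, n = 8) in vehicle. The exact permutation p was 0.0667 and 0.0444, and 2 arrays against 8 cannot give less than 0.0222. Each array was centred on its own median over all probe sets. Over the genes tested, the median log2 fold change was 0.31 at 2 h, 0.38 at 6 h, -0.17 at 16 h and 0.15 at 40 h in the time course. In experiment 1 it was within 0.05 of 0. How much of these shifts came from the centring stayed open. Time-course changes are given relative to these shifts. Adjusted p-values refer to the deposited values. Where the reference group had a mean signal below its array medians the size of a change is uncertain, and the log2 estimate is given without a fold.

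**Figure D1:**
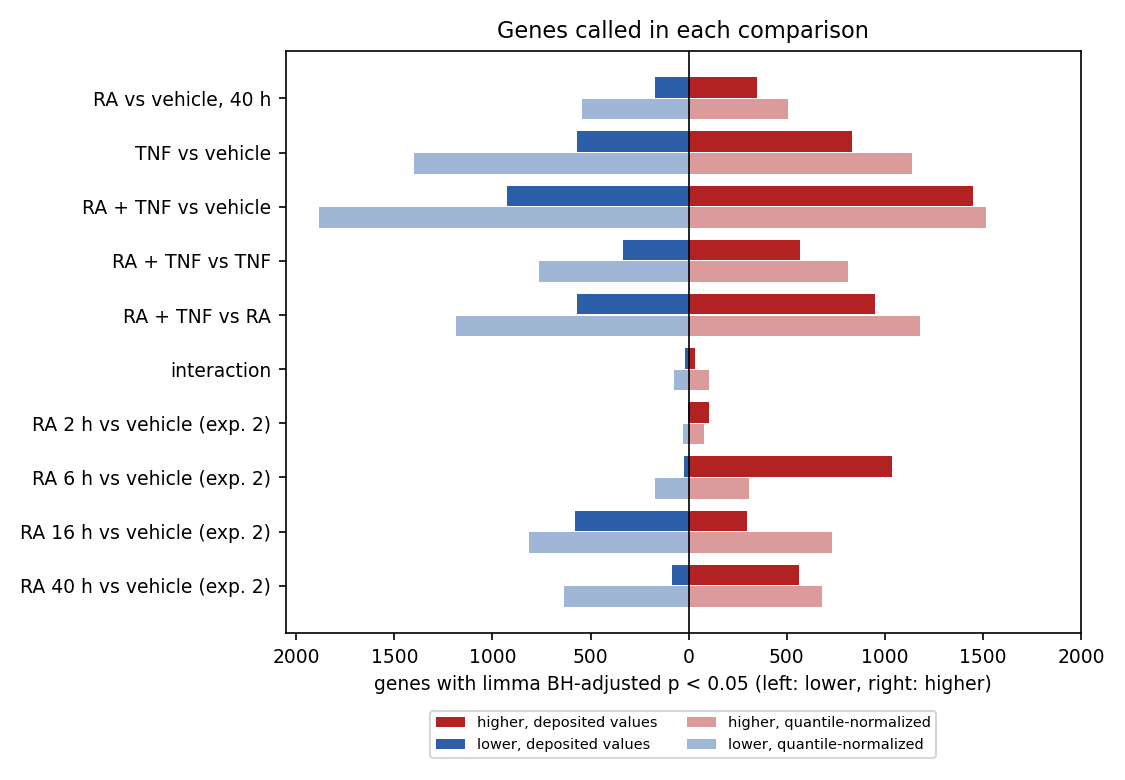
Number of genes with a limma BH-adjusted p under 0.05 in each comparison (horizontal axis, from 0 outward), higher to the right and lower to the left, from the deposited values (solid bars) and after quantile normalization (pale bars). At 6 h of RA the deposited values gave 1034 rises and 22 falls, and quantile normalization gave 306 and 171.

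RA alone at 40 h was compared with vehicle to find which transcripts RA changed (n = 5 against 6). CD1D, which presents lipid antigens to T cells, rose 27.1-fold (log2 4.76 ± 0.44, adjusted p = 4.42e-10). PTGES, a prostaglandin E synthase, rose by 5.27 ± 0.67 (4.96e-07), and DHRS3, which reduces retinaldehyde to retinol, rose 19.0-fold (4.25 ± 0.30, 6.9e-13). CD38, an enzyme that consumes NAD at the cell surface, rose 9.71-fold (3.28 ± 0.18, 1.2e-15). VIM, the intermediate filament vimentin, fell 4.56-fold (-2.19 ± 0.16, 1.48e-12), from a mean signal of 5350 ± 1110 units in vehicle (SD, n = 6) to 1120 ± 299 with RA (SD, n = 5).

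The other largest rises were KCNE1, a potassium channel subunit (4.84 ± 0.51), SYT2 (4.81 ± 0.58), the neurotrophin receptor NGFR (4.77 ± 0.74), the matrix glycoprotein THBS1 (4.76 ± 0.75), SPATA9 (4.45 ± 1.00) and the transcriptional repressor HIC1 (4.34 ± 0.56), with adjusted p-values from 1.03e-08 to 0.004. The largest falls were in SEMG1 (-3.71 ± 0.84, 0.0045), the sphingomyelin synthase SGMS2 (-3.23 ± 0.72, 0.00351), ZDHHC22 (-2.46 ± 0.59), the prolactin receptor PRLR (-2.42 ± 0.69), the neuronal pentraxin NPTX2 (-2.39 ± 0.50) and the collagen COL15A1 (-2.32 ± 0.51). In 14 of the 16 genes of largest change all RA arrays lay beyond every vehicle array. The monocyte markers ITGAM (1.19 ± 0.17, 3.34e-06) and CD14 (1.82 ± 0.44, 0.00782) rose, as did IL1B (1.16 ± 0.29, 0.0117). TNFAIP3 (0.21, adjusted p = 0.715) and TNF (-0.54, 0.736) did not pass. NFKBIA, the inhibitor of NF-kB, fell by 0.92 ± 0.17 (adjusted p = 0.0003), but its other probe set went the opposite way. TGM2, a transglutaminase, rose by 2.48 ± 0.65 (adjusted p = 0.0172), by 1.15 in array set 1 and 4.21 in set 2. CYP26A1 was below the brightness filter, with mean signals of 7.07 ± 4.77 units in vehicle (SD, n = 6) and 26.1 ± 22.5 with RA (SD, n = 5). CYP26B1 was below it too, at 6.9 ± 5.99 and 22.7 ± 16.1, as was RARB at 35.3 ± 25.9 and 38 ± 19.8.

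In the list of RA response in myeloid cells, 9 of 16 members rose and 1 fell, among them CD38, HIC1, the leukotriene receptor LTB4R (1.70 ± 0.22) and the nuclear receptor cofactor NRIP1 (1.09 ± 0.17). Adjusted over the list alone, 11 rose and 1 fell, and camera gave an adjusted p = 2.69e-12, or adjusted p = 0.0434 with an estimated correlation. Of 25 lipid handling genes 8 rose and 1 fell (10 and 2 adjusted over the list alone), including ALOX5AP (2.49 ± 0.20), which serves leukotriene synthesis, the scavenger receptor CD36 (1.52 ± 0.21), PTGS1 and APOC1. Its camera adjusted p was 7.78e-06, and adjusted p = 0.315 with an estimated correlation. Antigen presentation genes rose in 7 of 23 members, with none falling (13 adjusted over the list alone), as in CTSS (0.90 ± 0.16) and the immunoproteasome subunits PSMB10 (0.65 ± 0.14) and PSMB9 (0.74 ± 0.17); camera gave 5.2e-10, and adjusted p = 0.252 with an estimated correlation. The oxidative burst list had 3 rises among 11 (5 adjusted over the list alone), led by the NADPH oxidase subunit NCF1 (2.42 ± 0.22) and the kinase FGR (1.98 ± 0.21), with camera at 0.00199 and adjusted p = 0.315 with an estimated correlation. Among 16 matrix proteases and inhibitors 4 rose, with MMP2 at 2.55 ± 0.23 and CTSD at 1.38 ± 0.21 (4 adjusted over the list alone; camera 0.00108; adjusted p = 0.315 with an estimated correlation). Of 12 immature myeloid genes 2 fell and 1 rose: the granule protease CTSG fell by 1.38 ± 0.15, and the receptor FLT3 rose by 2.62 ± 0.24. Adjusted over the list alone 6 fell and 1 rose, and camera gave 0.0112, with adjusted p = 0.33 with an estimated correlation.

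Complement genes rose in 3 of 14 members, with SERPING1 at 2.44 ± 0.49 and CFP at 1.36 ± 0.24 (4 adjusted over the list alone; camera 3.34e-05; adjusted p = 0.131 with an estimated correlation). Monocyte and macrophage markers rose in 6 of 21 (7 up and 3 down adjusted over the list alone; camera 0.0027; adjusted p = 0.33 with an estimated correlation). Among 23 cytokines and chemokines 4 rose, including CCL2 (1.69 ± 0.37), and 1 fell (5 and 1 adjusted over the list alone; camera 0.0196; adjusted p = 0.324 with an estimated correlation). The cell cycle list had 1 fall among 32 members (4 adjusted over the list alone, 10 after quantile normalization; camera 8.47e-08; adjusted p = 0.33 with an estimated correlation). Both the retinoid metabolism list (1 of 11 rose, DHRS3) and the neutrophil granule list (1 of 6 rose, 2 fell, S100A8 by 1.63 ± 0.26) missed the camera threshold, with adjusted p = 0.093 and 0.547. The NF-kB list (4 up and 2 down of 21) and the interferon list (3 up and 3 down of 34) missed it at 0.426 each.

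With RA, 347 genes rose and 171 fell in limma, with 131 and 124 in array set 1 alone, 545 and 78 in set 2 alone, and 392 and 112 without RA 40 h replicate 2. Without RA 40 h replicate 5 there were 236 rises and 256 falls, so the excess of rises was not kept. After quantile normalization 508 rose and 546 fell, and 515 genes were called in the same direction both ways. Some calls were lost when single arrays were left out. TGM2 kept its call without 7 of the 11 arrays, each left out in turn (range 2.04 to 3.08), PRLR (-2.42) without 4 (range -2.88 to -1.70), and CAVIN3 (-2.04) without 9 (range -2.43 to -1.34), being lost without vehicle 40 h replicate 3 or RA 40 h replicate 3. CXCL8 rose by 1.13 ± 0.33 (adjusted p = 0.0383), but by 0.12 in array set 1 and 2.50 in set 2, and kept its call without 5 of the 11 arrays (range 0.64 to 1.37).

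TNF alone was compared with vehicle (n = 5 against 6). IGFBP3, which binds insulin-like growth factors, rose by log2 7.79 ± 0.43 (adjusted p = 1.11e-15), from 22.6 ± 18.5 signal units (SD, n = 6), below the array medians, to 3810 ± 1470 (SD, n = 5). The interferon-induced chemokine CXCL10 rose by 7.49 ± 0.51 (1.93e-13), and CXCL11 by 5.35 ± 0.64 (9.66e-08). The NF-kB feedback genes TNFAIP3 and NFKBIA rose 12.9-fold (3.69 ± 0.17, 1.08e-17) and 7.87-fold (2.98 ± 0.17, 1.58e-15). TNF's own transcript rose 9.63-fold (3.27 ± 0.46, 2.15e-06).

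The remaining largest rises were the cytokine IL32 (5.91 ± 0.61), the amino acid oxidase IL4I1 (5.84 ± 0.46), SLAMF8 (5.59 ± 0.40), ADAMDEC1 (5.52 ± 0.43) and EBI3 (5.40 ± 0.58), a subunit of interleukin 27. The largest falls were OLFML3 (-4.31 ± 0.90, adjusted p = 0.000778), GPA33 (-3.78 ± 0.67), the haematopoietic transcription factor NFE2 (-3.70 ± 0.66), NAPSB (-3.42 ± 0.35), SIM1 (-3.41 ± 0.65), GRIP1 (-3.30 ± 0.68), the phosphatase PTPN22 (-3.18 ± 0.50) and PDK4 (-3.17 ± 0.58), which restrains pyruvate oxidation. In all of these 16 genes every TNF array lay beyond every vehicle array. IL1B (2.41 ± 0.29), CD14 (2.40 ± 0.44), CXCL8 (2.00 ± 0.33), CD38 (0.97 ± 0.18) and ITGAM (0.78 ± 0.17) rose, with adjusted p-values of 0.00109 or less. DHRS3 was at -0.86 (adjusted p = 0.0535) and TGM2 did not pass (0.916).

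Of 34 interferon response genes 32 rose and none fell (33 adjusted over the list alone), with the antiviral genes MX1 at 3.27 ± 0.21, OAS2 at 3.01 ± 0.21 and OAS3 at 2.84 ± 0.23. Camera gave an adjusted p = 9.76e-50, and adjusted p = 0.00241 with an estimated correlation. Of 21 NF-kB targets 18 rose (18 adjusted over the list alone), including the adhesion molecule ICAM1 (4.84 ± 0.36) and the survival factor BCL2A1 (3.73 ± 0.29), at camera 1.66e-35 and adjusted p = 0.00023 with an estimated correlation. Among 23 cytokines and chemokines 14 rose and 2 fell (15 and 2 adjusted over the list alone), such as CCL2 (3.91 ± 0.37) and CCL5 (2.07 ± 0.20), at camera 2.56e-13 and adjusted p = 0.00156 with an estimated correlation. Immature myeloid genes fell in 6 of 12 members, with CTSG at -1.67 ± 0.15, PRTN3 at -1.60 ± 0.18 and SERPINB10 at -1.95 ± 0.31 (7 down and 1 up adjusted over the list alone; camera 1.31e-07; adjusted p = 0.0679 with an estimated correlation). The stress list rose in 10 of 18 (10 adjusted over the list alone), including VEGFA (2.58 ± 0.33) and the amino acid response genes CHAC1 (2.84 ± 0.48) and TRIB3 (1.45 ± 0.28), at camera 1.02e-07 and adjusted p = 0.115 with an estimated correlation. Sterol synthesis genes rose in 4 of 12 (6 adjusted over the list alone), led by HMGCS1 (1.27 ± 0.20) and DHCR7 (1.23 ± 0.21), at camera 3.07e-05 and adjusted p = 0.264 with an estimated correlation.

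Antigen presentation genes rose in 8 of 23 and fell in 1, with TAP1 at 1.46 ± 0.19, HLA-DRA at 1.63 ± 0.26 and CTSS at -0.94 ± 0.16 (10 and 1 adjusted over the list alone; camera 5.87e-05; adjusted p = 0.359 with an estimated correlation). Among 16 matrix proteases and inhibitors 5 rose, MMP9 most (3.72 ± 0.27), with 5 up and 1 down adjusted over the list alone (camera 0.00339; adjusted p = 0.342 with an estimated correlation). In the apoptosis and TNF receptor list 4 of 22 rose, including TNFRSF10B (1.21 ± 0.22) and BID (0.94 ± 0.17), and BCL2 fell by 1.28 ± 0.18 (5 and 1 adjusted over the list alone; camera 0.192). One of the other probe sets of BCL2 went the opposite way. No cell cycle gene passed in limma or adjusted over the list alone (camera 0.2), although 4 of 32 fell after quantile normalization. The cell cycle arrest list had 2 rises and 2 falls among 12 (camera 0.596). No epithelial or fibroblast marker passed (4 tested), and of 5 lymphocyte markers NKG7 rose (1.09 ± 0.25), a gene at 237 signal units on average.

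TNF raised 834 genes and lowered 570 in limma, with 372 and 186 changed at least 2-fold. After quantile normalization the counts were 1139 and 1400, and 1399 genes were called in the same direction both ways.

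RA plus TNF was compared with TNF alone to find what RA changed in cells under TNF (n = 5 against 5). The chemokine CCL20 rose by log2 6.16 ± 0.90 (adjusted p = 5.65e-06), from 12.5 ± 13.1 signal units, below the array medians, to 702 ± 354 (SD, n = 5 each). CD14, a receptor for bacterial lipopolysaccharide, rose 14.1-fold (3.82 ± 0.45, 9.8e-08), CXCL8, a neutrophil chemoattractant, 8.82-fold (3.14 ± 0.34, 1.29e-08) and IL1B 8.07-fold (3.01 ± 0.30, 3.02e-09). TNF's own transcript fell 4.89-fold (-2.29 ± 0.48, 0.00115), from 509 ± 128 to 132 ± 87.1 units (SD, n = 5 each). TNFAIP3 (0.13 ± 0.18, 0.784) and NFKBIA (0.18 ± 0.18, 0.68) did not pass.

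**Figure D2:**
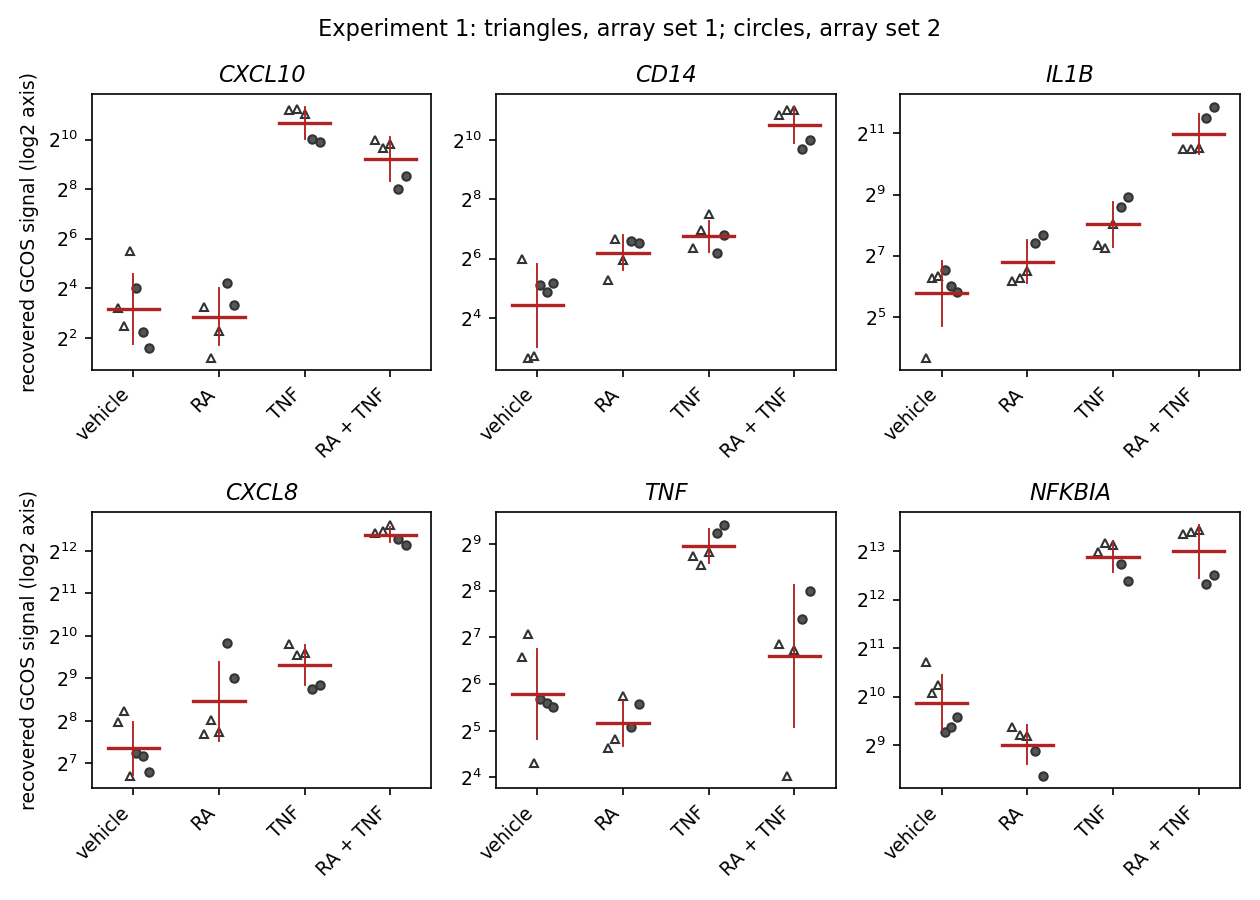
Recovered GCOS signal (log2 axis) of 6 genes on each array of experiment 1, by treatment. Triangles mark array set 1 and circles array set 2, and bars give the mean and SD of the log2 signals. Mean CXCL8 signals were 177 units with vehicle, 420 with RA, 663 with TNF and 5390 with both, and mean TNF signals were 65.7, 37.5, 509 and 132.

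DHRS3 (5.55 ± 0.31), the integrin subunit ITGA1 (5.43 ± 0.62), SYT2 (5.40 ± 0.61), THBS1 (5.39 ± 0.79), PTGES (5.38 ± 0.69), CHST15 (5.09 ± 0.51) and NGFR (4.80 ± 0.77) completed the 8 largest rises, and CD38 (2.37 ± 0.19) and TGM2 (2.77 ± 0.67) rose as well. The largest falls included ART3 (-2.98 ± 0.69, adjusted p = 0.00359), ARHGAP23 (-2.64 ± 0.58), the tyrosine kinase TEC (-2.63 ± 0.58), SYT17 (-2.58 ± 0.45), SYTL1 (-2.32 ± 0.44) and the Notch ligand DLL1 (-2.32 ± 0.45). In 14 of the 16 genes of largest change all arrays of the combined treatment lay beyond every TNF array. ITGAM did not pass (0.43, adjusted p = 0.146).

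Lipid handling genes rose in 11 of 25 members and fell in 1, with CD36 at 2.62 ± 0.22, APOC1 at 2.20 ± 0.19 and the nuclear receptor PPARG at 1.95 ± 0.29 (12 and 2 adjusted over the list alone; camera 3.57e-08; adjusted p = 0.146 with an estimated correlation). Oxidative burst genes rose in 6 of 11, including NCF1 (1.74 ± 0.23), NCF4 (1.30 ± 0.17) and CYBB (1.16 ± 0.24), with 6 adjusted over the list alone (camera 1.07e-05; adjusted p = 0.129 with an estimated correlation). Monocyte and macrophage markers rose in 7 of 21, such as CSF1R (1.45 ± 0.17), and KLF4 fell by 1.01 ± 0.19 (10 and 2 adjusted over the list alone; camera 1.68e-05; adjusted p = 0.195 with an estimated correlation). Matrix proteases and inhibitors rose in 7 of 16 and fell in 1, with MMP2 at 3.52 ± 0.23 and CTSB at 2.18 ± 0.19 (8 and 1 adjusted over the list alone; camera 2.4e-05; adjusted p = 0.146 with an estimated correlation). Interferon response genes fell in 6 of 34, including IRF7 (-1.38 ± 0.23), XAF1 (-1.08 ± 0.22) and MX1 (-0.99 ± 0.22), while IRF1 rose by 1.19 ± 0.19 (12 down and 2 up adjusted over the list alone; camera 1.07e-05; adjusted p = 0.377 with an estimated correlation). Immature myeloid genes fell in 5 of 12, with CTSG at -2.14 ± 0.16 and MYB at -0.91 ± 0.15, and FLT3 rose by 1.35 ± 0.25 (7 and 1 adjusted over the list alone; camera 1.07e-05; adjusted p = 0.146 with an estimated correlation). The RA response list had 9 rises and 1 fall among 16 (10 and 1 adjusted over the list alone; camera 3e-10; adjusted p = 0.0858 with an estimated correlation).

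The combined treatment gave 570 rises and 336 falls against TNF in limma, and 813 and 765 after quantile normalization, with 901 genes called in the same direction both ways. MIR142 (-2.42 ± 0.67) kept its call without 7 of the 10 arrays (range -3.10 to -1.92) and PRLR (-2.38 ± 0.72) without 3 (range -2.63 to -2.12). Of the 347 genes raised and 171 lowered by RA alone, 239 and 88 were also called in the same direction here.

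Against vehicle, RA plus TNF raised 1450 genes and lowered 924 (n = 5 against 6; 1518 and 1884 after quantile normalization; 2318 called in the same direction both ways). CD14 rose by log2 6.22 ± 0.44 (adjusted p = 9.57e-14), IL1B 42.9-fold (5.42 ± 0.29, 1.39e-16) and CXCL8 35.2-fold (5.14 ± 0.33, 7.88e-15), and DHRS3 (4.68 ± 0.30), TNFAIP3 (3.82 ± 0.17), CD38 (3.33 ± 0.18), NFKBIA (3.15 ± 0.17), TGM2 (2.58 ± 0.65) and ITGAM (1.21 ± 0.17) rose too. TNF's transcript was at 0.98 (adjusted p = 0.144). Antigen presentation genes rose in 16 of 23, with HLA-DRA at 2.88 ± 0.26 and CD74 at 1.81 ± 0.19 (20 adjusted over the list alone; camera 3.02e-12; adjusted p = 0.0595 with an estimated correlation). Immature myeloid genes fell in 8 of 12, CTSG by 3.81 ± 0.15, and 1 rose (8 and 1 adjusted over the list alone; camera 4.93e-11; adjusted p = 0.0235 with an estimated correlation). In the apoptosis list 8 of 22 rose and 2 fell, BCL2 by 2.64 ± 0.18 (9 and 2 adjusted over the list alone; camera 0.138).

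Against RA alone the combined treatment raised 952 genes and lowered 568 (n = 5 against 5; 1181 and 1185 after quantile normalization; 1505 called in the same direction both ways). The balance differed between the array sets, with 994 rises and 269 falls in set 1 alone and 292 and 490 in set 2 alone. CD14 rose by 4.40 ± 0.45 (adjusted p = 3.41e-09), IL1B by 4.26 ± 0.30, NFKBIA by 4.07 ± 0.18 (9.26e-19), CXCL8 by 4.01 ± 0.34 and TNFAIP3 by 3.60 ± 0.18. DHRS3 (0.43, 0.443) and CD38 (0.05, 0.919) did not pass. TNF's transcript rose by 1.52 ± 0.48 (adjusted p = 0.0301), and kept its call without 2 of the 10 arrays (range 1.27 to 2.14). Of 34 interferon response genes 28 rose (28 adjusted over the list alone; camera 5.65e-31; adjusted p = 0.0142 with an estimated correlation). Neutrophil granule genes rose in 4 of 6 and fell in 1, with MMP9 at 4.40 ± 0.29 and the calprotectin subunits S100A8 at 2.09 ± 0.27 and S100A9 at 1.38 ± 0.22 (4 and 1 adjusted over the list alone; camera 0.00019; adjusted p = 0.0899 with an estimated correlation).

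The interaction asked whether the RA effect differed with and without TNF (21 arrays). G0S2, an inhibitor of fat breakdown, rose 4.67-fold more with RA under TNF (log2 difference 2.22 ± 0.32, adjusted p = 0.000166), with mean signals of 192 ± 53.4 units in vehicle (SD, n = 6), 380 ± 135 with RA, 366 ± 36.6 with TNF and 3460 ± 1250 with both (SD, n = 5 each). The steroid-metabolising reductases AKR1C1 and AKR1C2 showed the opposite difference (-2.49 ± 0.30, 1.15e-05, and -2.41 ± 0.32, 3.67e-05). AKR1C1 rose by 2.12 ± 0.21 with RA alone (adjusted p = 1.94e-09) and was at -0.36 ± 0.22 with RA under TNF (adjusted p = 0.406). AKR1C1 and AKR1C2 are near-identical genes whose probe sets may cross-hybridise, so they are not independent.

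Positive differences were also called for the acute-phase protein gene ORM1 (3.72 ± 0.80, adjusted p = 0.0209), ATP13A2 (3.08 ± 0.56, 0.0038), EMP2 (1.86 ± 0.28, 0.000358), CXCL8 (2.02 ± 0.47, 0.037), IL1B (1.85 ± 0.42, 0.0322) and NFKBIA (1.10 ± 0.24, 0.0278). Negative differences were called for BMP8B (-1.63 ± 0.23, 0.000143), PWAR6 (-1.72 ± 0.34, 0.00911), DDIT4L (-2.37 ± 0.57, 0.0492) and LINC02987 (-2.19 ± 0.50, 0.0318). CD14 (1.99, 0.236) and TNF (-1.75, 0.429) did not pass, so a difference of their RA effects was not shown. CXCL8 differed by 2.85 in array set 1 and 0.90 in set 2, and IL1B by 2.26 and 1.33. With each of the 21 arrays left out in turn, the call was kept without 8 for CXCL8 (range 1.77 to 2.51), 9 for IL1B (1.56 to 2.18), 10 for NFKBIA (0.98 to 1.28), 4 for DDIT4L (-2.73 to -2.09) and 10 for LINC02987 (-2.55 to -1.88). ORM1 kept it without 19 (3.05 to 4.24), and lost it without RA plus TNF replicate 2 or TNF replicate 5. Without cross-hybridising probe sets CXCL8 was represented by another probe set, at 1.45, and was not called. The other probe set of NFKBIA and that of LINC02987 went the opposite way.

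In total 33 genes had a positive and 20 a negative interaction in limma, and 53 were called in the same direction after quantile normalization, among 102 and 75. With eBayes without a trend 11 genes were called, and with no array set covariate 7. Array set 1 alone gave 38 positive and 19 negative calls, and array set 2 alone 3 and 13. Of the 33, 28 were also higher with RA plus TNF than with TNF, and of the 20, 15 were lower. The count was 80 without RA 40 h replicate 5, 34 without RA 40 h replicate 1 or TNF replicate 1, 32 without RA plus TNF replicate 4, 30 without RA 40 h replicate 3 or TNF replicate 3, and 28 without RA plus TNF replicate 3. The interferon list had a median difference of -0.34 with no member called, in limma or adjusted over the list alone (camera 7.91e-05; adjusted p = 0.768 with an estimated correlation).

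The time course asked when RA changes appeared. No vehicle well was harvested at 2 h or 6 h. At these times an effect of RA cannot be told apart from an effect of the harvest time. After 2 h (n = 2 against 8) CD1D was raised 9.95-fold relative to the shift of the genes tested (log2 3.31, SE 0.23, adjusted p = 4.15e-12), and the activating receptor CD300LB by log2 3.02 (SE 0.40, 3.42e-06). The interferon regulatory factor IRF1 (1.56, SE 0.20, 4.69e-07) and DDIT4 (1.85, SE 0.23, 4.69e-07), an inhibitor of mTOR signalling, rose as well. HIC1 was raised by 4.38 (SE 0.78, 0.000449), STOX2 by 3.53 (SE 0.71, 0.00175), DHRS3 4.39-fold (2.13, SE 0.53, 0.0112) and CD38 2.17-fold (1.12, SE 0.25, 0.000876). The 3 genes that fell were TNNT3 (-2.90, SE 0.55, 0.0101), ZNF554 (-2.19, SE 0.41, 0.0133) and FOSL2 (-1.34, SE 0.21, 0.00765).

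At 2 h 106 genes rose and 3 fell in limma, and 79 and 27 after quantile normalization, with 81 called in the same direction both ways. Without RA 2 h replicate 1 the count of calls was 52, and without replicate 2 it was 43, where the remaining array is assumed to vary like the other groups. In these refits, on the deposited scale, HIC1 was lost without replicate 1 (range over the arrays left out 4.35 to 4.99), CD38 without replicate 2 (1.24 to 1.62), ZNF554 without replicate 1 (-2.47 to -1.28), and STOX2 (3.31 to 4.05), DHRS3 (2.12 to 2.63), TNNT3 (-2.88 to -2.43) and FOSL2 (-1.09 to -0.96) without either. The other probe set of ZNF554 went the opposite way, and DHRS3 was not called after quantile normalization (adjusted p = 0.183). In the RA response list 3 of 16 rose (5 adjusted over the list alone; camera 0.0378; adjusted p = 0.584 with an estimated correlation). Camera placed the interferon list lower (4.24e-06, and 0.584 with an estimated correlation), and the immature myeloid list too (0.000153, and 0.346). Of 28 interferon genes 1 rose and none fell in limma, and none of 13 immature myeloid genes was called. Later in the time course camera placed the interferon list higher. At 16 h it gave 5.9e-06 (0.254 with an estimated correlation), with 3 of 28 members raised and none lowered. At 40 h it gave 8.37e-05 (0.315), with 4 raised and none lowered, whereas in experiment 1 the list missed the threshold at 40 h.

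After 6 h (n = 2 against 8) HIC1 was raised by log2 5.54 relative to the shift (SE 0.78, adjusted p = 3.35e-06), CD1D 23.3-fold (4.54, SE 0.23, 8.7e-16), DHRS3 18.4-fold (4.20, SE 0.53, 2.92e-07) and CD38 5.78-fold (2.53, SE 0.25, 7.97e-10). FGR (2.53, SE 0.22), DDIT4 (2.13, SE 0.23), CCL2 (2.10, SE 0.32), PRAM1 (2.09, SE 0.29), NCF1 (1.98, SE 0.19), IRF1 (1.59, SE 0.20), ALOX5AP (1.47, SE 0.22) and NRIP1 (1.39, SE 0.24) rose, with adjusted p-values of 3.84e-06 or less. ADAM33, a membrane protease, fell by 3.52 (SE 0.41, 2.81e-06). CYP26B1, which degrades RA and lay below the filter, had 62.2 ± 1.71 signal units at 6 h (SD, n = 2) and 2.94 ± 1.70 in vehicle at 16 h (SD, n = 5). In vehicle at 40 h, over both array sets, it had 6.9 ± 5.99 units (SD, n = 6). SEMA3C (4.48, SE 1.24, 0.0136) and TGM2 (3.18, SE 0.64, 0.000377) lost their calls without RA 6 h replicate 2 (ranges on the deposited scale 4.29 to 5.44 and 3.08 to 4.05), as did LYZL4 (-3.08, SE 0.66, 0.00973; range -3.04 to -2.36). TCP10L (-3.13, 0.0312) lost its call without RA 6 h replicate 1 or vehicle 40 h replicate 4 (range -4.30 to -1.21), and was not called after quantile normalization (adjusted p = 0.0579).

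The deposited values gave 1034 rises and 22 falls at 6 h in limma, and quantile normalization gave 306 and 171, with 324 called in the same direction both ways. Without RA 6 h replicate 2 there were 148 calls and without RA 6 h replicate 1 there were 1926, where the remaining array is again assumed to vary like the other groups, and without vehicle 16 h replicate 2 there were 1800. The RA response list had 9 rises among 16 (6 after quantile normalization; 11 adjusted over the list alone; camera 1.41e-08; adjusted p = 0.0516 with an estimated correlation).

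**Figure D3:**
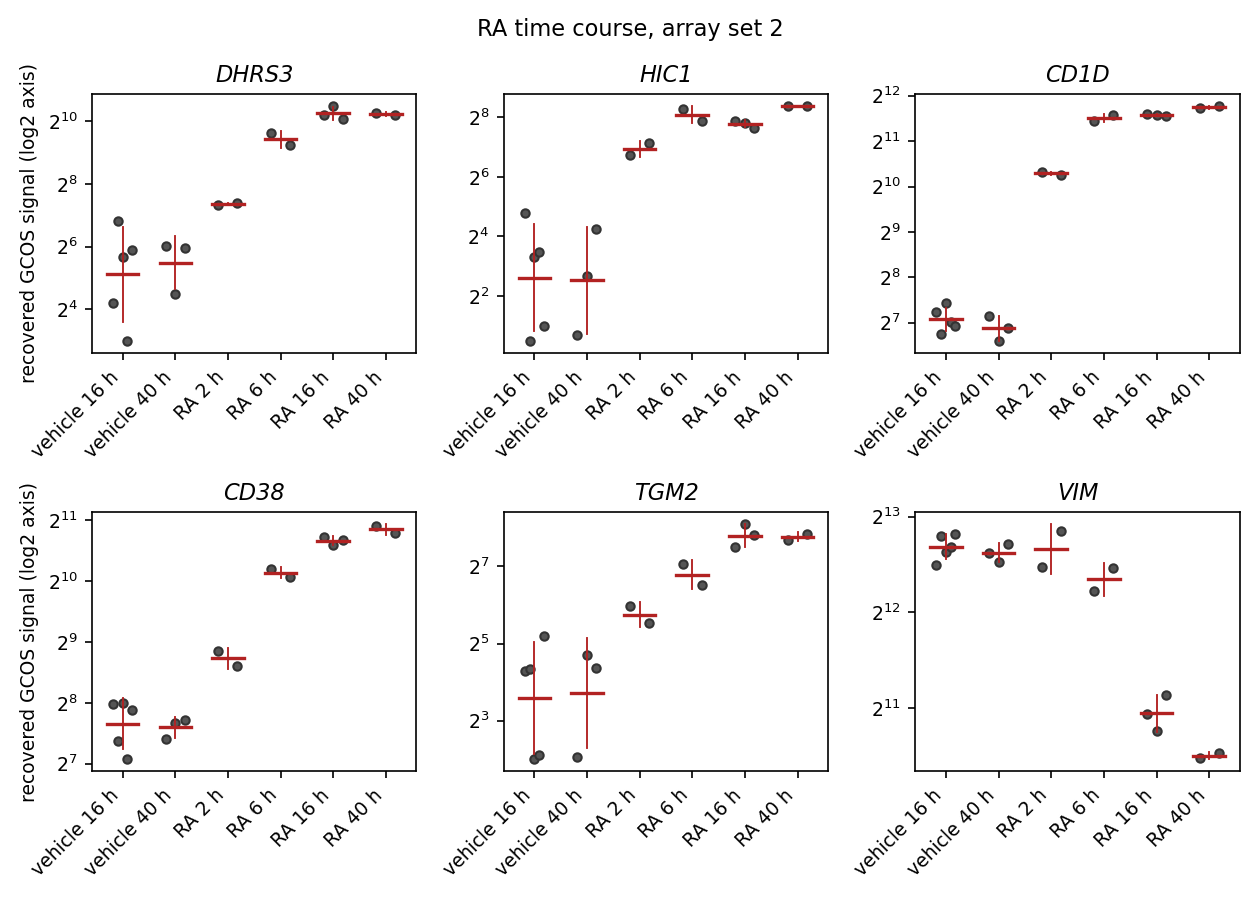
Recovered GCOS signal (log2 axis) of 6 genes on the arrays of array set 2, by RA exposure, with vehicle harvested at 16 h and 40 h. Circles are arrays, and bars give the mean and SD of the log2 signals. CD1D signals were 1230 to 1280 units at 2 h and 108 to 172 in vehicle at 16 h, and VIM signals were 1730 to 2260 at 16 h and 5770 to 7210 in vehicle at 16 h.

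After 16 h (n = 3 against 8) KCNE1 was raised by log2 5.72 relative to the shift (SE 0.82, adjusted p = 2.4e-05), HIC1 by 5.24 (SE 0.67), DHRS3 32.7-fold (5.03, SE 0.45, 4.05e-09), NGFR by 4.85 (SE 0.77), CD1D 24.3-fold (4.60, SE 0.19, 2.08e-16), SYT2 by 4.53 (SE 0.71) and TGM2 by 4.19 (SE 0.55). In 11 of the 16 genes of largest change all RA arrays lay beyond every vehicle array. CD38 (3.06, SE 0.21), CXCL8 (1.68, SE 0.26, 0.000238) and ITGAM (1.21, SE 0.17) rose, whereas CD14 (0.22, adjusted p = 0.958) did not pass. VIM fell by 1.86 on the deposited scale (SE 0.17, 2.47e-09), and was at 0.09 at 6 h (SE 0.20, adjusted p = 0.763). The largest falls whose calls were kept without each array were TOX-DT (-3.96, SE 0.74, 0.000343), ERVMER34-1 (-2.76, SE 0.65, 0.00408), the transcription factor DMRT1 (-2.73, SE 0.52, 0.000391) and the peroxisomal oxidase ACOX2 (-2.59, SE 0.44, 6.5e-05).

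Of 32 cell cycle genes 12 fell at 16 h (21 adjusted over the list alone, 19 after quantile normalization), including the replication factors MCM4 (-0.69, SE 0.19) and MCM7 (-0.54, SE 0.18) and the proliferation marker MKI67 (-0.53, SE 0.16) relative to the shift. Camera gave 6.47e-09, and adjusted p = 0.254 with an estimated correlation, and these 3 calls were lost without RA 16 h replicate 1, where the log2 change on the deposited scale was -0.62, -0.57 and -0.62, against -0.85, -0.71 and -0.70 with all arrays. The RA response list had 7 rises and 2 falls among 16 (9 and 2 adjusted over the list alone; camera 2.59e-13; adjusted p = 0.00958 with an estimated correlation). None of the 4 erythroid and megakaryocyte markers passed at any time point. At 16 h 295 genes rose and 580 fell in limma, and 731 and 815 after quantile normalization, with 838 called in the same direction both ways. The count of calls was 1674 without vehicle 16 h replicate 5, 451 without RA 16 h replicate 1 and 477 without RA 16 h replicate 2. ADH1C (4.36, SE 1.24, 0.0346) lost its call without RA 16 h replicate 2 (4.52 on the deposited scale), and SEMA3C (4.30, SE 1.06, 0.0148) without replicates 2 or 3 (3.96 each).

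The 40 h arrays of array set 2, tested within the time course (n = 2 against 8), gave DHRS3 31.8-fold (4.99, SE 0.53, adjusted p = 2.57e-08), TGM2 by log2 4.14 (SE 0.64), CD38 9.35-fold (3.22, SE 0.25), CXCL8 5.22-fold (2.38, SE 0.31, 5.15e-07) and ITGAM 2.89-fold (1.53, SE 0.20) above the shift. In limma 563 genes rose and 85 fell, and 682 and 638 after quantile normalization, with 627 called in the same direction both ways. Without RA 40 h replicate 5 there were 266 calls, under the same assumption for the 1 array left. No cell cycle gene of 32 was called, in limma or adjusted over the list alone, and 23 fell after quantile normalization (camera 3.55e-12; adjusted p = 0.224 with an estimated correlation). Complement genes rose in 4 of 13, among them CD55 (1.27, SE 0.23, on the deposited scale), with 6 adjusted over the list alone (camera 8.6e-06; adjusted p = 0.048 with an estimated correlation).

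Vehicle arrays at 40 h were compared with those at 16 h in array set 2 (n = 3 against 5), since both served as the reference. No gene passed in limma, 409 had an unadjusted p under 0.05, and quantile normalization gave 1. Without vehicle 16 h replicate 5 there were 2 calls and without vehicle 40 h replicate 5 there were 3. The comparison does not cover harvest at 2 h or 6 h.

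RA effects were compared between arrays that had no array in common, RA at 40 h against vehicle within array set 1 and RA at 16 h against vehicle at 16 h. Across 12404 genes the log2 fold changes correlated at r = 0.299 (rho = 0.222), and 63.3% had the same sign. Genes are not independent replicates, so no p is given. Of 210 and 396 calls, 112 were shared, all in the same direction, against 3.4 for independent lists. RA at 40 h in array set 1 against RA at 40 h in array set 2 gave r = 0.319 over 12390 genes. Only 53.4% of these genes had the same sign. Of 208 and 682 calls there, 126 were shared, 124 of them in the same direction, against 5.8 for independent lists.

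RA and TNF effects at 40 h correlated across genes at r = 0.222, and 81 genes rose and 38 fell with both. RA raised 40 genes that TNF lowered, and lowered 37 that TNF raised. Both comparisons used the same 6 vehicle arrays. Simulated arrays of the same design, vehicle included, with no group changed gave a mean r of 0.456. The covariance was 0.0738, against a mean of 0.0618 in the simulations, a difference of 0.012, and a highest value of 0.0686. Genes varied independently in these simulations, so whether the difference exceeds chance was not settled. With the vehicle arrays split between the comparisons, r was 0.0188, and 47 genes rose and 18 fell with both, against 11.6 and 2.56 for independent lists. RA then raised 13 genes that TNF lowered, and lowered 37 that TNF raised.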

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

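The tests on recovered signals, on values centred on the genes tested, on the ACTB ratio and on the lowest signals were chosen only after the results were seen. Quantile normalization, the separate array sets and leaving out arrays were planned as alternatives, and were applied to these patterns afterwards.

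Single arrays far from the rest of their group were found in 14 of 218 gene and group pairs (6.4%), and chance alone marks about 1 in 20 groups. Each is given as its gap to the nearest array over the range of the group. In vehicle at 40 h, replicate 1 was far from the others for ADAMDEC1 (0.852), GPA33 (0.674) and IL1B (0.748; -1.50 against 0.85 for the nearest array), replicate 4 for DHRS3 (0.817) and replicate 6 for SYT2 (0.789). Among the 8 vehicle arrays of the time course, vehicle 40 h replicate 6 was far for STOX2 (0.672) and vehicle 16 h replicate 4 for TNF (0.54). With RA at 40 h, replicate 2 was far for NPTX2 (0.839) and replicate 5 for SGMS2 (0.711). With TNF, replicate 2 was far for EBI3 (0.791) and PDK4 (0.724), replicate 3 for ATP13A2 (0.759) and replicate 5 for CCL20 (0.713). With both, replicate 4 was far for PWAR6 (0.765). ADAMDEC1, EBI3 and GPA33 kept their TNF calls, NPTX2 and SGMS2 their RA calls, and ATP13A2 and PWAR6 their interaction calls without each array in turn.

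A difference between groups was tested as the RA effect with TNF minus the RA effect without TNF, in log2. It was positive for ORM1 (3.72), ATP13A2 (3.08), G0S2 (2.22), CXCL8 (2.02), EMP2 (1.86), IL1B (1.85) and NFKBIA (1.10). It was negative for AKR1C1 (-2.49), AKR1C2 (-2.41), DDIT4L (-2.37), LINC02987 (-2.19), PWAR6 (-1.72) and BMP8B (-1.63).

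The first pattern weighed was the excess of rises over falls after 6 h of RA. Centring each array on its own median predicted fewer rises on the recovered signals, and the share of called genes that rose was 69.9% there, so centring may account for part of the excess. The ratio of the 3' to the 5' ACTB probe set as the whole cause was excluded, since 442 genes rose and 13 fell with it as a covariate (97.1% rising). It may account for part of the excess, as the counts without it were 1034 and 22. Whether RA raised more genes than it lowered stayed open, at 64.2% after quantile normalization. No vehicle well was harvested at 6 h, so the harvest time as a cause cannot be told apart from RA here.

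The second pattern was the larger rise of IL1B and CXCL8 with RA under TNF. The calls did not depend on the scaling of the arrays, with 10 of 10 kept under 5 other scalings. Each of these scalings kept all 53 interaction calls, so the test could hardly have failed for these genes. In array set 2 alone the difference for IL1B was 1.33 ± 0.35, 3.77 SE above 0, which argues against an effect of array set 1 alone. For CXCL8 it was 0.90 ± 0.37, 2.41 SE above 0 without adjustment, so an effect mainly of array set 1 stayed open. Over all genes array set 2 alone gave 3 positive interaction calls, and array set 1 alone 38. Signals near the floor were excluded for CXCL8, whose lowest vehicle or RA array had 104 units, and for IL1B, where 1 of 11 such arrays lay under its array median (vehicle 40 h replicate 1, 12.7 units) and the call was kept without it, at 2.18. Both calls lay near the threshold and were lost when any of 13 arrays for CXCL8 or 12 for IL1B was left out, with estimates of 1.77 to 2.51 and 1.56 to 2.18 over all 21 refits; the other CXCL8 probe set, at 1.45 and not called, left CXCL8 open, and a greater RA response under TNF remains a hypothesis for IL1B.

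The third pattern was the lower TNF transcript with RA plus TNF than with TNF. The call did not depend on the scaling (5 of 5 kept). These scalings kept 891 to 905 of the 906 calls of this comparison, so that test could hardly have failed. A single array (10 of 10 calls kept) and array set 1 alone (-5.05 SE in array set 2) were excluded. A fall of the transcript under RA is consistent with these tests. Whether transcription or decay changed was not analysed here.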

How the results depend on the processing

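Most alternatives were planned; the recovered signals, the centring on the genes tested and the ACTB ratio were chosen only after results were seen. Over the named genes and all settings other than leaving out arrays, 10180 results stayed the same, 738 became weaker, 372 stronger and 3 reversed; for lists 909 stayed the same, 93 became weaker and 18 stronger. The reversals were HLA-F in RA at 40 h (-0.24) and ZNF554 at 2 h (0.47) without cross-hybridising probe sets, where another probe set stood for the gene, and ATF4 in RA at 40 h in array set 2 alone (0.62). The cause of the other changes was not tested, except that a subset has fewer arrays and that every probe set tests more than 1 probe set per gene. The counts of calls follow.

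For RA at 40 h (518) the count was 1054 after quantile normalization, 780 over every probe set, 226 with no array set covariate, 255 in array set 1 alone, 1050, 1004 and 1081 on recovered signals with 20, 2 and 80 units added, and 969 centred on the genes tested. In the same order TNF (1404) gave 2539, 2126, 652, 649 (887 in array set 2 alone), 2549, 2501, 2588 and 2355. RA plus TNF against vehicle (2374) gave 4067 over every probe set, 1302 with no covariate, 1357 in array set 1 alone and 3565 with 80 units added. Against TNF (906) it gave 1578 after quantile normalization, 1659 over every probe set, 402 with no covariate, 1633, 1568 and 1665 on recovered signals and 1528 centred on the genes tested. Against RA (1520) it gave 2366, 2606, 797, 782 in array set 2 alone, 2466, 2389, 2491 and 2353. The interaction (53) gave 177 after quantile normalization, 11 with eBayes without a trend, 7 with no covariate, 16 in array set 2 alone, 190, 164 and 248 on recovered signals and 163 centred on the genes tested. With the ACTB ratio as a covariate the count was 499 for RA, 1346 for TNF and 48 for the interaction. RA plus TNF then gave 1757 against vehicle, 706 against TNF and 1208 against RA. 

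At 2 h (109) the count was 70 without a trend. At 6 h (1056) it was 477 after quantile normalization, 560 without a trend, 650 with only the groups compared, 495, 485 and 493 on recovered signals, 471 centred on the genes tested, 455 with the ACTB ratio and 519 with only vehicle arrays harvested at 16 h. At 16 h (875) it was 1546, 1496, 1464 and 1526, 1371 and 541 for quantile normalization, recovered signals, centring and vehicle at 16 h. At 40 h in the time course (648) it was 1320, then 1282, 1258 and 1281, then 1257. For vehicle at 40 h against 16 h (0) it was 1 after quantile normalization, over every probe set and without a trend. 

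The lists past the camera threshold with an estimated correlation numbered 1 for RA at 40 h, 3 for TNF, 5, 0 and 4 for RA plus TNF against vehicle, TNF and RA, 0 for the interaction, 0 at 2 h, 0 at 6 h, 1 at 16 h and 2 at 40 h in the time course; after quantile normalization 6 passed at 2 h. The agreement of RA effects (r = 0.299) was 0.112 without a filter, 0.572 with the stricter brightness filter, 0.214 over every probe set, 0.407 with 20 and 0.493 with 80 units added. The overlap of RA and TNF effects (r = 0.222) was 0.334 without a filter, 0.129 with the stricter filter and 0.136 with 80 units added. 

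With each array left out in turn the ranges were 398 to 542 for RA at 40 h, 1162 to 1474 for TNF, 2034 to 2499, 716 to 908 and 1210 to 1665 for RA plus TNF against vehicle, TNF and RA, 28 to 80 for the interaction, 43 to 162 at 2 h, 148 to 1926 at 6 h, 451 to 1674 at 16 h, 266 to 732 at 40 h in the time course, 0 to 3 for vehicle, 0.254 to 0.308 for the agreement and 0.197 to 0.268 for the overlap. Over named genes 8007 such results stayed the same, 434 became weaker and 92 stronger.

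Replicate numbers did not pair the arrays of experiment 1. With the array set removed, same-numbered deviations correlated there at a median r of 0.00551 (0 of 30 pairs over 0.1). In experiment 2 the median r was 0.0471 (5 of 15 pairs over 0.1), against -0.012 for the other pairs, so a weak pairing stayed open there. With a replicate block the counts were 53 at 2 h and 371 at 6 h, and no other count of genes moved by over 1.5 times. Single-gene calls also changed, such as CXCL8 in the interaction (2.04, not called). The planned pseudocounts on the deposited values were not run, because these values are already logs. Fits of the interaction with only the groups compared use the same arrays and were not run again. Signals near the floor limit what can be seen: fold changes of genes absent in 1 group depend on it.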

Other observations

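The random splits, and the correlation of the ACTB ratio with the array medians, were chosen only after the results were seen. The interactions, fold changes and refits without single arrays were planned.

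Several genes changed with the combined treatment in ways not yet described. The lysosomal protease CTSB had mean signals of 1350 units with vehicle, 2250 with RA, 1250 with TNF and 5420 with both, and its RA effect was larger under TNF (interaction 1.43 ± 0.26, limma adjusted p = 0.0038). NRIP1 (1.36 ± 0.25, 0.00424) and TNFAIP8 (1.39 ± 0.27, 0.00745) had the same pattern. DHRS9, a retinol dehydrogenase, had the opposite one (-1.09 ± 0.24, 0.0261; call kept without 16 of the 21 arrays, range -1.22 to -0.94). CCL20 had mean signals of 3.6 units with vehicle, 11.7 with RA, 12.5 with TNF and 702 with both, but its interaction did not pass (4.87, 0.0785).

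The complement gene C1QA rose by log2 4.41 ± 0.81 with RA plus TNF against TNF (limma adjusted p = 0.000235). CXCL10 (-1.41, 0.11) and CXCL11 (-2.07, 0.0518) did not pass there.

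In array set 2 the log2 ratio of the 3' to the 5' ACTB probe set correlated with the recovered median signal at r = 0.586 (21 arrays, permutation p = 0.005, adjusted p = 0.01; rho = 0.575; r = 0.626 without the 2 farthest arrays). In array set 1 r was 0.172 (12 arrays, permutation p = 0.6). The permutations took no account of group. In array set 2 the RA 2 h and 6 h arrays were low in both measures, with ratios of 0.126 to 0.299 and medians of 18.9 to 25.6 units. A relation within groups therefore cannot be told apart from a difference between groups here.

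Random splits of the same arrays were used to ask whether chance could give as many calls. For genes, the real grouping gave more calls than any other split drawn in 5 comparisons of experiment 1. These were RA at 40 h (518 calls, highest other split 394), TNF (1404 and 883) and RA plus TNF against vehicle (2374 and 1577), TNF (906 and 38) and RA (1520 and 621). In each, 1 of 100 splits was at or above the real count, the real grouping itself. The median of the other splits was 0 calls in each. Labels were drawn without regard to the array set, whereas the real groups were spread over both sets. The splits thus make chance unlikely for these counts, but do not strictly exclude it. In the 3 comparisons with vehicle, the highest other split set all 5 treated arrays and vehicle 40 h replicate 1 against the other 5 vehicle arrays. Such a split carries the treatment effect with its sign reversed, so its count is not a level given by chance. For RA at 16 h 2 of 100 splits reached the real count (875; 1286), so a wrong grouping gave more calls than the real one. The count on the deposited values does not by itself set the RA grouping apart. The split with 1286 calls kept RA 16 h replicates 1 and 2 together and exchanged replicate 3 with vehicle 16 h replicate 5. It gave 111 calls on the recovered signals, against 1496 for the real grouping, and why it gave more on the deposited values was not tested. The splits decide nothing for the interaction (53; 1401; 2 of 100), since relabelling over 4 groups mixes the effects of TNF and RA into it. They decide nothing for vehicle at 40 h against 16 h either (0; 79; 56 of 56), since every split reaches 0. For the number of gene lists past the camera threshold chance was not excluded for RA at 40 h (10; 12; 5 of 100), TNF (10; 14; 9), RA plus TNF against vehicle (14; 16; 8), against TNF (10; 12; 14), against RA (13; 15; 9) or RA at 16 h (11; 13; 11). The same splits served for the lists, so the reversed ones enter these counts. The median of the other splits was 3, 4, 6, 3, 5 and 4 lists, in the same order. Lists thus commonly passed camera at the preset correlation under wrong groupings too, and such a pass is weak support by itself. The interaction (6; 16; 43) was again not decided. For the correlation of the RA effects between separate arrays chance was excluded (r = 0.299; 0.228; 1 of 100).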
